A study of Mus musculus with 41 samples.

How the data were processed

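The series measured where the androgen receptor (AR), a steroid-activated transcription factor, and 3 DNA-binding factors (FOXA1, HNF4A and AP2A) sat on the genome of mouse prostate, kidney and caput epididymis, by chromatin immunoprecipitation followed by sequencing (ChIP-seq). Per the labels, tissues came from male mice of the ICR strain aged 8 to 12 weeks. The mice were intact, or castrated and killed 2 h after testosterone or vehicle. Of the 41 samples, 28 were immunoprecipitated for AR or for 1 of the 3 factors. Those were represented by 23 peak lists with 479214 peaks in all. The 7 IgG samples and the 6 samples immunoprecipitated for the histone marks H3K4me1 and H3K27ac were not analysed here as lists of their own.

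Libraries were amplified for 20 PCR cycles and fragments of about 250 bp were isolated, per the labels' protocols. Reads were mapped with Bowtie to mouse build mm9, per the submitters' processing notes; its version is not given in the sources used here. Per the series' design text, parallel libraries of some replicates were merged, a merged IgG data set served as the control, and all states except the castrated ones were done in biological duplicate. The peak caller is not given in the sources used here. Per the file headers, every peak has a position, a length, a summit, a count of tags, a fold enrichment and an FDR in percent. The deposited tag count is the whole number of tags inside the peak, with no normalization. The deposited fold enrichment is a ratio of tags over background as the authors' peak caller gave it. The deposited FDR is a percent and came from the same caller. A further deposited column is a score per peak whose header name was lost to a spreadsheet error. Its place, its minimum of 50 in most lists and its pile-up at 3100 are those of a p score on the negative log10 scale, and it was used only to rank, stratify or filter peaks within 1 list. Score and fold are the authors' values for each peak, and their sizes were not compared between lists. The number of peaks at an FDR of 1% or less was given to describe each list and was not tested between lists.

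Replicates 1 and 2 of prostate AR with testosterone, the castrated prostate AR list and the castrated kidney HNF4A list each stand for 2 parallel libraries, and the other lists were taken as 1 library each. Whether the castrated AP2A list covers 1 or both of its 2 libraries is not given in the sources used here. AR with androgen had 2 replicate lists per tissue, as did FOXA1 in prostate with testosterone and AP2A in the intact epididymis. Kidney HNF4A, every factor outside its own tissue and every castrated state had 1 list. Total reads per library are not given in the sources used here, so the depth behind a list was described by its number of peaks and its median tags per peak. Wilson 95% intervals were given for shares and cover counting error only. Replicate values were printed side by side, since 2 lists give no useful SD. Peaks of 1 list are not biological replicates, so p-values computed over sites describe these lists.

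An AR site was a replicate 1 peak that overlapped a replicate 2 peak of the same tissue by at least 1 bp, in the androgen-exposed state (testosterone for prostate and kidney, intact for epididymis). It kept the replicate 1 interval and summit. A factor with 2 lists counted at a site when both lists had a peak there. A site was called tissue-only when it met no AR site of the other tissues, and shared when it met AR sites of both. FOXA1 was treated as the own factor of prostate, HNF4A of kidney and AP2A of epididymis. Own and other factors were compared over the same AR sites with the two-sided exact McNemar test (6 tests). Tissue-only and shared sites were compared with the two-sided Fisher's exact test (3 tests). Overlap beyond chance was tested one-sided against 1000 circular shifts of the sites within the mapped extent of each chromosome (12 pairs), with a smallest possible p of 0.001. In a first run this test took factor peaks of replicate 1 matched in replicate 2; it was changed after that run to sites met by both factor lists, as in the other tests, and no call changed. Castrated and androgen-exposed factor lists were compared with the exact McNemar test. The plan named 3 adjusted tests, and since each replicate was tested against the castrated list, 5 were adjusted. The fold enrichment of AR peaks with and without the own factor was compared within each AR list on the log2 scale by a two-sided permutation test of the difference of means with 100000 resamples (6 tests). Castrated AR peaks were set against the AR sites with the same shifts (3 tests). Differences between tissues were tested two-sided on log odds ratios with a normal approximation, or with Fisher's exact test for shares (12 tests). Adjusted p-values are Benjamini-Hochberg values within each family. Where a p fell below what double precision holds, its log10 was computed and is printed.

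The rule for named sites was fixed before the data were examined. It took, per tissue, the 5 tissue-only AR sites with the best mean rank of the score over both replicates, the 5 shared sites with the best mean rank over all 6 AR lists, and the 3 own-factor peaks at AR sites with the best mean rank. It would also have named peaks of a castrated AR list of 30 or fewer peaks, and no list was that short. Ties were broken by the mean rank of fold enrichment. Sites are given by mm9 position, 1-based as in the files. No mm9 gene annotation or genome sequence was used here, so nearby genes, exon or intron status and motifs were not analysed here, and the planned tests of gene lists and motifs were not run.

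Alternatives were a 50% reciprocal overlap, summits at most 200 bp apart, sites of 100 bp each side of the summit, a score of 100 or more, an FDR of 1% or less, lists of equal length, the union of the AR replicates, each AR replicate list alone, leaving out sites found in 18 or more of the 23 lists, autosomes only, chance positions drawn from the union of all peaks, and either factor replicate in place of both. Either factor replicate was planned for the comparison of own and other factors and added for the others. After the data were seen, 4 more were added: each factor replicate list alone, replicate 2 coordinates for AR sites, and tissue-only sites without any AR peak in the other tissues. The permutation test used 1000 resamples in the alternatives. The 5 regions found in 18 or more lists were kept in the main results.

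The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. The code was tested on simulated lists of 3800 AR sites per tissue. For the contrast of tissue-only and shared sites, planted shares of 40% and 25% were recovered as 39.2% to 40% and 23.4% to 27.1%. For the enrichment contrast a planted log2 difference of 0.5 came out at 0.52 to 0.55. A first simulation without any effect had positions on a coarse grid, on which the shift test called most runs, and it was replaced by one with positions at any base. In the 200 runs of 2000 sites without any effect, the shift test called 3%, the permutation test 6% and Fisher's test 2.5% at the threshold of 0.05.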

Results

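AR binding was mapped in 3 androgen-responsive mouse tissues: the prostate, the kidney and the caput (head) of the epididymis, the duct in which sperm mature, called epididymis from here on. Binding of 3 candidate collaborating factors was mapped in the same tissues. FOXA1 is a forkhead factor that can bind closed chromatin, HNF4A is a nuclear receptor of liver, gut and kidney epithelium, and AP2A belongs to the AP-2 family of epithelial regulators. The 41 samples fell into 31 groups of antibody, tissue and hormone state. AR had 4 samples from prostate with testosterone, 2 from kidney with testosterone, 2 from the intact epididymis, and 2, 1 and 1 from castrated animals in the same order. FOXA1 had 2 samples from prostate with testosterone, HNF4A 1 from kidney with testosterone and AP2A 2 from the intact epididymis, with 1, 2 and 2 from castrated animals. Each of these factors had 1 sample in each of the other tissues. Samples entered the comparisons as 23 peak lists, in which parallel libraries had been merged.

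AR lists from androgen-exposed animals held 38204 and 76711 peaks in prostate replicates 1 and 2, 22135 and 17716 in kidney, and 38686 and 24154 in epididymis. The castrated AR lists were shorter, with 41 peaks in prostate, 7555 in kidney and 3834 in epididymis. The lowest score was 80.3 in the castrated prostate list and 50 in the castrated kidney and epididymal lists. Whether these counts rest on the same cut is therefore not known. Median tags per AR peak were 19 and 12 in the prostate replicates, 42 and 44 in kidney, and 37 and 48 in epididymis. The prostate lists thus had fewer tags per peak than the other androgen-exposed AR lists. At an FDR of 1% or less, 19.5% and 21.5% of the peaks remained in the prostate replicates, 76.8% and 74.2% in kidney, and 88.0% and 76.2% in epididymis. The median FDR was 78.7% and 5.78% in prostate replicates 1 and 2. Median tags in the castrated AR lists were 8 in prostate, 20 in kidney and 9 in epididymis.

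FOXA1 peaks were numerous only in prostate, with 32176 and 37367 in the testosterone replicates against 1780 in kidney and 3427 in epididymis. HNF4A gave 16539 peaks in kidney with testosterone, 1162 in prostate and fewest in epididymis. AP2A gave 33528 and 29543 peaks in the intact epididymis, and also 20932 in kidney and 5653 in prostate. Peaks of FOXA1 and HNF4A outside their own tissues were weakly supported in these lists. At an FDR of 1% or less, 5 of the kidney FOXA1 peaks, 0 of the epididymal FOXA1 peaks, 1 of the prostate HNF4A peaks and 3 of the epididymal HNF4A peaks remained. The prostate AP2A list kept 3 peaks at that FDR, and the kidney AP2A list kept all 20932.

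**Figure D1:**
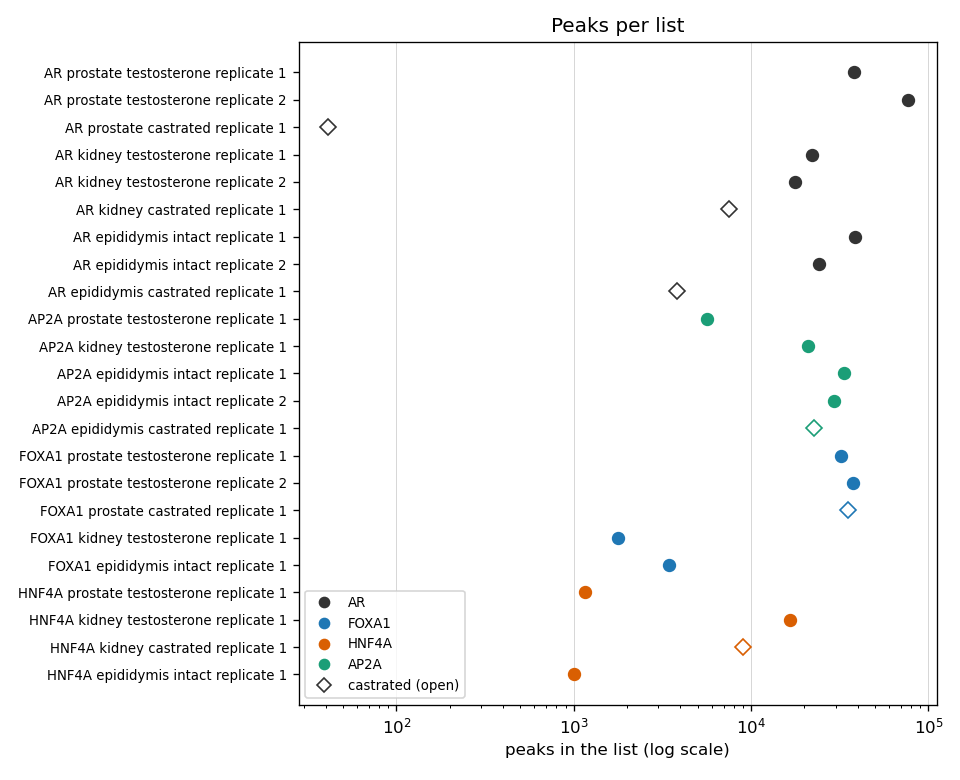
Number of peaks in each of the 23 lists (horizontal axis, log scale), coloured by antibody, with open diamonds for castrated animals. AR lists of castrated animals, at 41, 7555 and 3834 peaks, lie below every androgen-exposed AR list, the shortest of which has 17716.

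The first question was how AR sites are divided among the tissues. Prostate had 14125 AR sites present in both replicates, kidney 13575 and epididymis 22767. Replicate peaks matched less well in prostate, where 37.0% of replicate 1 and 18.4% of replicate 2 peaks were found in the other list. The shares were 61.3% and 76.8% in kidney, and 58.9% and 93.6% in epididymis. Over the alternatives, the prostate replicate 1 share ranged from 31.8% to 71.4%, while epididymal replicate 1 reached 58.8% at most, so that order turned. Prostate replicate 2 stayed at 15.8% to 32.2%, below every kidney and epididymal value. Most AR sites met no AR site of the other tissues, though a peak in 1 list of another tissue does not count against this. Such tissue-only sites made up 54.9% of the prostate sites (95% interval 54.1% to 55.7%), 64.5% of the kidney sites (63.7% to 65.3%) and 65.7% of the epididymal sites (65.1% to 66.3%). Sites shared by all 3 tissues numbered 1911 in prostate, 1860 in kidney and 1861 in epididymis, which was 13.5%, 13.7% and 8.17% of each tissue's sites.

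With sites present in both AR replicates, prostate and epididymis shared more of their AR sites than either shared with kidney. Of the prostate AR sites, 40.0% met an epididymal AR site and 18.6% met a kidney AR site, and 30.6% of the kidney sites met an epididymal site. Circularly shifted positions gave 0.868%, 0.577% and 1.12%, so that the observed overlaps were 46.2-fold, 32.2-fold and 27.3-fold higher (one-sided shift permutation test, adjusted p = 0.0012 for each, at the smallest p the shifts can give). Shared sites carried stronger AR peaks. The median fold enrichment in replicate 1 was 28.9 at shared and 12.2 at prostate-only sites, 16.3 and 8.2 in kidney, and 33.7 and 16.9 in epididymis. With peaks drawn at random from the union of all lists in place of shifted positions, the 3 overlaps were 3.78-fold, 2.95-fold and 2.79-fold above chance. With 1 AR replicate list per tissue they were 11.4 to 22.3-fold, 9.03 to 14.5-fold and 16.5 to 23.1-fold above the shifts. The lead of prostate with epididymis over kidney with epididymis was thus not kept at 11.4-fold.

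**Figure D2:**
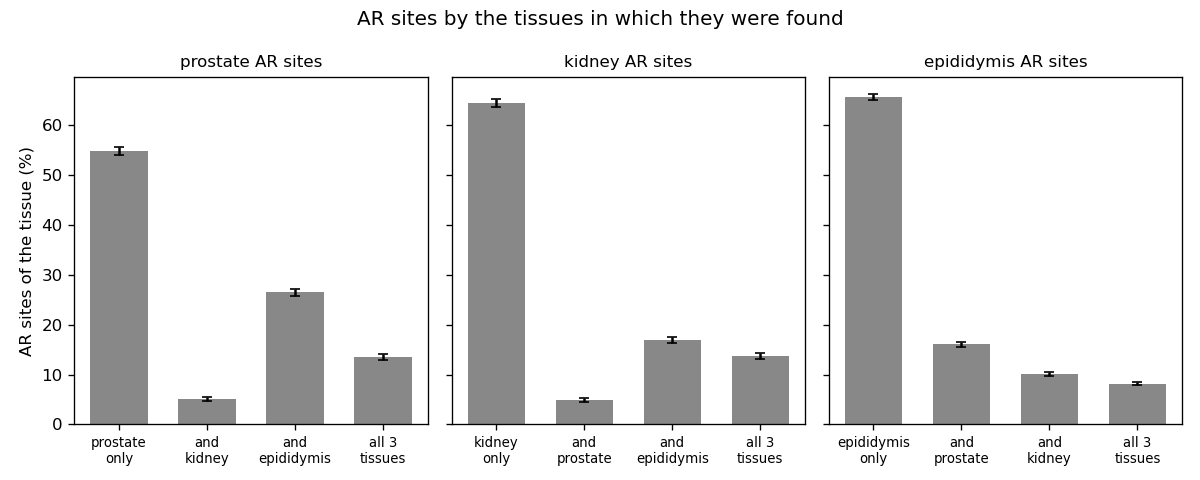
Share of each tissue's AR sites (vertical axis, %) found in that tissue only, in 1 other tissue or in all 3, with Wilson 95% intervals for counting error. Sites of 1 tissue are the largest class in each panel, and prostate overlaps epididymis (26.5% of its sites in these 2 tissues only) more than kidney (5.04%).

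The tissue-only AR sites ranked best by score can be located in mm9. The score piles up at 3100, and higher values were ranked above the pile-up. The first-ranked epididymal site scored 3233.06 in replicate 1 with 274 tags, the fewest of the 5 sites there. The best-ranked sites are thus not necessarily the strongest. In prostate the 5 best-ranked sites lay on chromosome 8 from 27993090 to 27993529, chromosome 1 from 40519657 to 40519949, chromosome 12 from 81005734 to 81006576, chromosome 3 from 101518498 to 101518981 and chromosome 15 from 85410285 to 85410744. FOXA1 peaks in both replicates covered all 5, and AP2A covered 1. Their fold enrichment ranged from 73.4 to 142 in replicate 1 and from 43.9 to 85.4 in replicate 2. In kidney the 5 sites lay on chromosome 18 from 50885503 to 50886577, chromosome 1 from 56672251 to 56672913, chromosome 16 from 48421954 to 48423288, chromosome 15 from 91488202 to 91489243 and chromosome 8 from 122541448 to 122542276. HNF4A peaks covered all 5, and the AR fold enrichment ranged from 54.6 to 74.1 in replicate 2. In epididymis they lay on chromosome 1 from 186115002 to 186115436, chromosome 13 from 102013421 to 102014078, chromosome 8 from 96748173 to 96749036, chromosome 16 from 20873988 to 20874699 and chromosome 5 from 44520463 to 44521675. AP2A covered 3 of these 5.

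The 5 best-ranked shared sites, by prostate coordinates, lay on chromosome 17 from 28557024 to 28558294, chromosome 8 from 67404453 to 67405249, chromosome 2 from 71000747 to 71001355, chromosome 4 from 105872038 to 105873277 and chromosome 16 from 20784578 to 20785244. FOXA1, HNF4A and AP2A each had a peak in at least 1 tissue at 4 of the 5.

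The next question was which factor accompanies AR in which tissue. In prostate, FOXA1 had peaks at 34.0% of the AR sites (33.2% to 34.8%), AP2A at 8.62% and HNF4A at 0.0566%. In kidney, HNF4A had peaks at 49.0% (48.1% to 49.8%), AP2A at 13.8% and FOXA1 at 0.619%. In epididymis, AP2A had peaks at 25.1% (24.6% to 25.7%), FOXA1 at 0.382% and HNF4A at 0.0351%. With 1 AR replicate list alone, 11.02% to 19.7% of the prostate AR peaks had FOXA1 and 3.46% to 4.92% had AP2A. By factor replicate, FOXA1 reached 38.2% and 44.4% of the prostate sites, and AP2A 29.2% and 27.7% of the epididymal sites. By this rule none of the 3 factors was counted at 63.4% of the prostate, 45.3% of the kidney and 74.6% of the epididymal AR sites. Prostate FOXA1 and epididymal AP2A had to be in both lists. Sites with a peak in only 1 of these lists are thus among those without that factor. Kidney factors had 1 list each, so the kidney share was counted less strictly.

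Each tissue's own factor exceeded both other factors over the same AR sites. FOXA1 exceeded AP2A by 25.4 percentage points in prostate (95% interval 24.6 to 26.2), with 3942 sites holding FOXA1 without AP2A and 360 the opposite (exact McNemar test, log10 adjusted p = -759). HNF4A exceeded AP2A by 35.2 percentage points in kidney (34.2 to 36.2; 5528 against 753 sites, log10 adjusted p = -892). AP2A exceeded FOXA1 by 24.8 percentage points in epididymis (24.2 to 25.3; 5681 against 45 sites, log10 adjusted p = -1610). The other 3 differences, against HNF4A in prostate and epididymis and against FOXA1 in kidney, were 33.9, 25.1 and 48.4 percentage points. The lists of the other factors were shorter than that of the own factor, except that of AP2A in kidney, which was longer than that of HNF4A (20932 against 16539 peaks). HNF4A in prostate and epididymis, and FOXA1 in kidney and epididymis, had fewer peaks than there were AR sites with the own factor. The direction of those differences was thus largely set by list length. The lists of each tissue were also shortened to the length of its shortest list. That was HNF4A in prostate (1162 peaks), FOXA1 in kidney (1780 peaks) and HNF4A in epididymis. The differences over AP2A were then 0.715 points in prostate (3.38% against 2.67%) and 7.79 points in kidney (9.82% against 2.03%). That over FOXA1 in epididymis was 1.68 points. Each kept its direction (exact McNemar tests, highest adjusted p = 0.00026). Lists this short can reach only a small part of the AR sites, so the fall in points follows in part from the cut. FOXA1 and AP2A in prostate were not compared at the full length of the AP2A list. With 1 AR replicate list alone, the difference over AP2A was 7.56 to 14.8 points in prostate and 23.1 to 29.1 points in kidney.

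**Figure D3:**
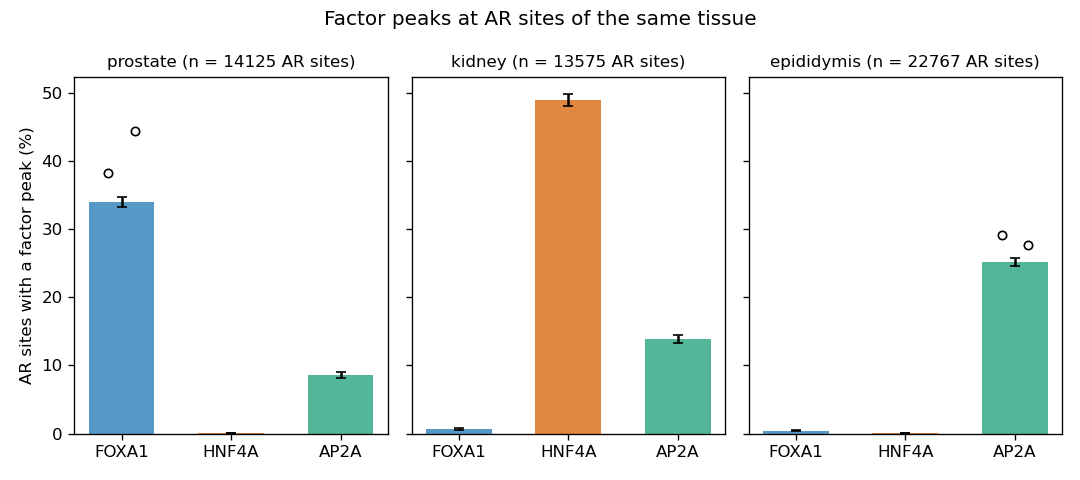
Share of AR sites (vertical axis, %) with a FOXA1, HNF4A or AP2A peak in each tissue. Bars need a peak in every list of the factor, error bars are Wilson 95% intervals for counting error, and open circles give the 2 replicate lists where there are 2. FOXA1 leads in prostate at 34.0%, HNF4A in kidney at 49.0% and AP2A in epididymis at 25.1%.

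Factor peaks met AR sites more often than shifted positions did. The excess was 48.2-fold for FOXA1 in prostate, where the shifts gave 0.705%, 63.0-fold for HNF4A in kidney and 22.1-fold for AP2A in epididymis (adjusted p = 0.0012 for each, permutation by shifts). AP2A was also above the shifts in prostate, 36.4-fold, and in kidney, 11.6-fold (adjusted p = 0.0012 by the same permutation). FOXA1 reached 10.6-fold in kidney and 4.07-fold in epididymis on 84 and 87 sites, and HNF4A 2.57-fold in prostate on 8 sites (permutation by shifts, adjusted p = 0.02). HNF4A in epididymis, also on 8 sites, did not pass (1.38-fold, permutation adjusted p = 0.22). With 1 AR replicate list alone, the excess in prostate was 16.9 to 31.1-fold for FOXA1 and 15.3 to 22.3-fold for AP2A. Against random draws from the union of all peaks, the excess was 3.35-fold for FOXA1 in prostate, 6.3-fold for HNF4A in kidney and 2.17-fold for AP2A in epididymis. AP2A reached 3.34-fold in prostate, close to FOXA1 there, and 1.36-fold in kidney. On that scale FOXA1 in kidney and epididymis fell to 0.751-fold and 0.252-fold, and HNF4A in prostate to 0.105-fold. The union holds the peaks of the tested factor list itself, so values under 1 do not by themselves show depletion at AR sites.

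Seen from the factors, 41.2% of the kidney HNF4A peaks lay on AR sites, against 16.6% and 16.7% of the FOXA1 peaks in the prostate replicates and 20.1% and 21.3% of the AP2A peaks in the epididymal replicates. The best-ranked of these factor peaks were FOXA1 on chromosome 9 from 61751994 to 61752541, HNF4A on chromosome 11 from 94019507 to 94020249 and AP2A on chromosome 19 from 44960911 to 44962037, followed by FOXA1 on chromosome 12 from 81005774 to 81006554 and on chromosome 9 from 61656000 to 61657008, HNF4A on chromosome 16 from 76453781 to 76454574 and on chromosome 10 from 66383662 to 66384695, and AP2A on chromosome 9 from 44292770 to 44294645 and on chromosome 17 from 56258970 to 56260562. The last of these overlaps 1 of the 5 regions found in 18 or more of the 23 lists. The first FOXA1 peak scored 3187.88 in replicate 1, above the pile-up at 3100, with 246 tags. Its rank need not mean that it is the strongest.

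A further comparison asked whether the own factor marks the tissue-only part of AR binding. HNF4A was more frequent at kidney-only than at shared AR sites, 54.8% of 8762 against 41.0% of 1860, a difference of 13.8 percentage points (11.4 to 16.3; Fisher's exact test, adjusted p = 6e-27). FOXA1 was more frequent at prostate-only sites, 39.2% of 7756 against 32.1% of 1911, a difference of 7.09 points (4.73 to 9.45; exact test, adjusted p = 9.1e-09). AP2A went the other way in epididymis, with 24.9% of 14964 epididymis-only and 32.1% of 1861 shared sites, a difference of -7.27 points (-9.51 to -5.04; exact test, adjusted p = 5.2e-11). The FOXA1 difference changed sign in 4 of its 16 alternatives. With the replicate 1 list alone it was -7.65 points, with replicate 2 alone -18.9 points, with their union -14.7 points and with a 50% reciprocal overlap -3.53 points. Stricter peaks widened it, to 16.0 points at an FDR of 1% or less, 12.2 points at a score of 100 or more and 11.3 points with lists of equal length. The HNF4A difference fell to 1.17 points with the union of the AR replicates (exact test, adjusted p = 0.17, against 1.1e-37 to 0.014 in its other alternatives) and to 6.81 and 2.39 points with the replicate 2 and the replicate 1 list alone.

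**Figure D4:**
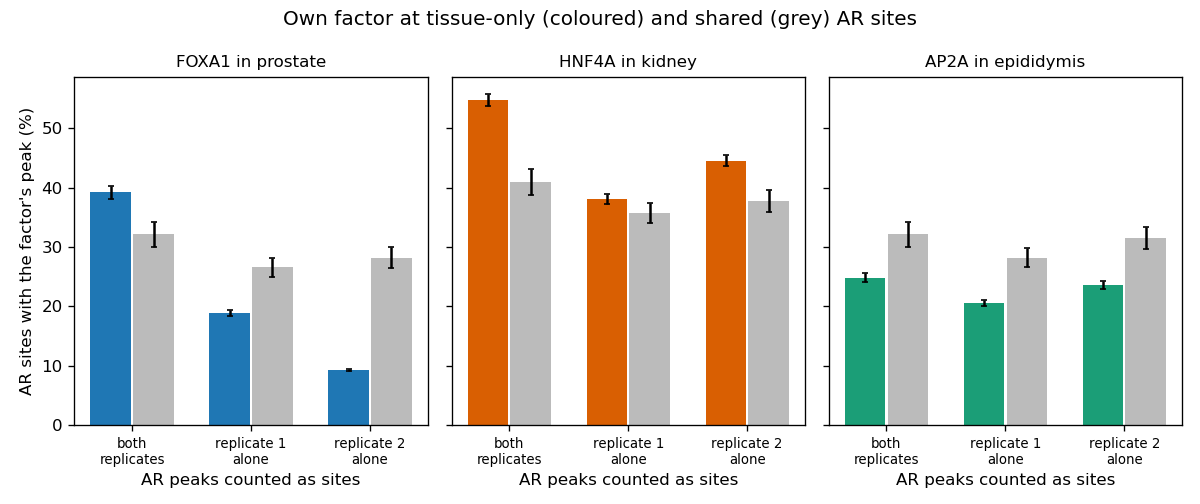
Share of AR sites (vertical axis, %) with the tissue's own factor, for tissue-only (coloured) and shared (grey) sites, when a site needs both AR replicates or is any peak of replicate 1 or of replicate 2 alone; error bars are Wilson 95% intervals for counting error. HNF4A stays higher at kidney-only sites and AP2A lower at epididymis-only sites in all 3 settings, whereas FOXA1 is higher at prostate-only sites with both replicates (39.2% against 32.1%) and lower with either list alone.

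AR peaks that coincided with the own factor were more enriched within each AR list. The difference in mean log2 fold enrichment was 0.35 (SE 0.013) and 0.36 (SE 0.011) for FOXA1 in the prostate replicates, 0.38 (SE 0.012) and 0.26 (SE 0.013) for HNF4A in kidney, and 0.30 (SE 0.014) and 0.22 (SE 0.015) for AP2A in epididymis. All 6 differences had an adjusted p of 1e-05, the smallest the permutation test can give. The sizes varied with the peaks admitted: the lowest values over the alternatives were 0.11 and 0.26 in the prostate replicates, 0.089 and 0.058 in kidney, at a score of 100 or more, and 0.16 in each epididymal replicate. The median fold enrichment of prostate replicate 1 AR peaks was 12.7 with FOXA1 and 10.4 without it. In epididymis replicate 1 it was 14.4 with AP2A and 11.3 without.

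Castrated animals were compared to see whether the factors already sit on AR sites without androgen. Part of the sites were occupied in the castrated state in each tissue. FOXA1 covered 30.02% of the prostate AR sites in castrated mice (29.3% to 30.8%), HNF4A 25.9% of the kidney sites (25.2% to 26.6%) and AP2A 13.8% of the epididymal sites (13.4% to 14.3%). Every androgen-exposed list covered more. FOXA1 was higher by 8.23 points (7.55 to 8.90) in testosterone replicate 1 and by 14.4 points (13.7 to 15.1) in replicate 2. HNF4A was higher by 23.1 points (22.3 to 23.8) with testosterone, and AP2A by 15.4 points (14.9 to 15.9) and 13.9 points (13.4 to 14.4) in the intact replicates (exact McNemar tests, log10 adjusted p = -126, -331, -811, -807 and -705). The castrated lists held 35437 FOXA1, 9029 HNF4A and 22604 AP2A peaks, so the HNF4A and AP2A lists were shorter than their androgen-exposed counterparts. With lists of equal length the differences were 9.45 and 13.6 points for FOXA1, 8.88 points for HNF4A, and 9.69 and 9.83 points for AP2A. Of the AR sites with HNF4A in 1 kidney list only, 3232 had it with testosterone and 98 in the castrated list. With 1 AR replicate list alone the FOXA1 differences were 1.21 to 2.52 points in replicate 1 and 2.38 to 6.88 points in replicate 2. Over all alternatives the difference for FOXA1 replicate 1 ranged from 0.724 to 10.3 points. The castrated state had 1 list per tissue, so these tests compare lists and have no replicate check on that side.

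**Figure D5:**
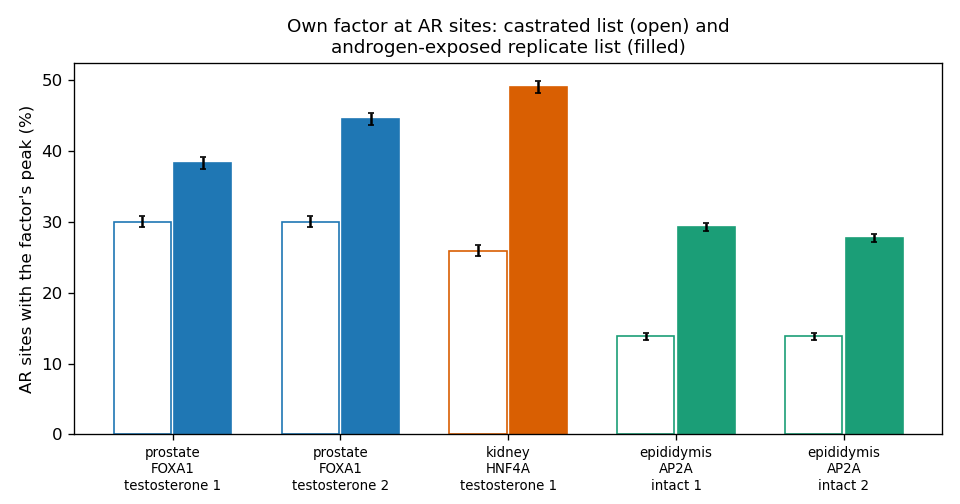
Share of AR sites (vertical axis, %) with the tissue's own factor in the castrated list (open bars) and in each androgen-exposed replicate list (filled bars), with Wilson 95% intervals for counting error; the same castrated list is drawn beside each replicate. Filled bars exceed open bars in all 5 comparisons, from 38.2% against 30.02% for FOXA1 replicate 1 to 49.0% against 25.9% for HNF4A.

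AR peaks of castrated animals were compared with the AR sites of the same tissue. In epididymis 1919 of the 3834 castrated peaks, 50.1% (48.5% to 51.6%), lay on AR sites, 59.3-fold above the shifted positions (adjusted p = 0.0015, permutation by shifts). That share was 24.7% with 50% reciprocal overlap, 31.2% with lists of equal length and 85.3% at a score of 100 or more. In kidney 501 of 7555 did, 6.63% (6.09% to 7.21%), 8.19-fold above the shifts (same permutation, adjusted p = 0.0015), and the share ranged from 3.75% to 12.3% over the alternatives, with 8.13% to 10.8% on the peaks of 1 AR replicate list. In prostate 1 of 41 did, 2.44% (0.432% to 12.6%), which the shifts could give (permutation adjusted p = 0.14). Against draws from the union of all peaks, the epididymal share stayed 4.72-fold above chance (permutation, adjusted p = 0.003), but the kidney share equalled chance at 6.67% (permutation adjusted p = 0.86, against 0.0015 in its other alternatives). No peak of the castrated kidney list had an FDR of 1% or less, the lowest being 2.88%. All 3834 peaks of the castrated epididymal list did.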

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

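The 2 tests on castrated kidney AR peaks, and the odds ratios of prostate and kidney within 5 score strata, were chosen after the result was seen, as was leaving FOXA1 replicate 1 out of the test of list length; the other tests of explanations were fixed before their results were seen. The contrasts below differed between tissues by a two-sided test of the difference itself (12 tests, adjusted p between 1.4e-105 and 0.001 where double precision held one). Only the castrated AR share of prostate minus kidney did not differ (-4.19 points, Fisher's exact test, adjusted p = 0.52). Each tissue has its own factor and antibody, and androgen came as testosterone after castration in prostate and kidney but from intact animals in epididymis, so tissue, factor and hormone regime differ together.

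The odds of finding the own factor at tissue-only over shared AR sites were 1.36 in prostate, 1.75 in kidney and 0.699 in epididymis. The ratio of these odds ratios was 1.95 for prostate over epididymis, 2.5 for kidney over epididymis and 0.78 for prostate over kidney. These values are for sites present in both AR replicates. With 1 AR list alone the odds ratio of FOXA1 was 0.645 in replicate 1 and 0.261 in replicate 2, on the side of AP2A (0.66 and 0.672), and the FOXA1 difference was also negative with the union and with 50% reciprocal overlap (-14.7 and -3.53 points). Stricter peaks set them further apart, at 16.0 points for FOXA1 and -6.97 for AP2A with an FDR of 1% or less, and at 12.2 and -4.90 with a score of 100 or more. Stronger AR peaks at shared sites could account for the AP2A pattern: within 5 strata of the score the odds ratio was 0.976 (0.873 to 1.09). AP2A sites common to several tissues stay open: without sites that have an AP2A peak in kidney or prostate the odds ratio was 1.16 (1.01 to 1.33), but this removes 25.1% of the shared and 5.73% of the epididymis-only sites and so raises the ratio by construction. Wider intervals at shared sites were argued against as the whole cause, because with 100 bp each side of the summit the difference was still -3.44 points, though nearer 0 than the -7.27 with full intervals (Fisher's exact test, adjusted p = 0.0014; 4.2e-32 to 0.035 over all its alternatives). Within score strata the odds ratios of FOXA1 in prostate and HNF4A in kidney were 2.5 (2.2 to 2.83) and 3.88 (3.4 to 4.41) with both replicates, but that of FOXA1 was 1.74 (1.58 to 1.92) with replicate 1 alone and 0.57 (0.518 to 0.627) with replicate 2 alone. How FOXA1 stands to AP2A thus depended on how AR sites were defined and which peaks were admitted, whereas HNF4A and AP2A lay further apart within the strata than without them, also with replicate 1 alone (3.18 against 0.999) and replicate 2 alone (3.27 against 0.921), which argues against AR peak strength as the cause of that difference and leaves factor, tissue and hormone regime open.

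The gain of the own factor at AR sites with androgen, taken as the ratio of sites gained to sites lost against the castrated list, was 2.81 and 5.26 for FOXA1, 33.0 for HNF4A and 15.6 and 13.5 for AP2A. Prostate replicates 1 and 2 stood at 0.0853 and 0.159 of the kidney ratio, and epididymal replicates 1 and 2 at 0.473 and 0.408 of it. Prostate stood at 0.18 of epididymis for replicates 1 and at 0.391 for replicates 2. Castrated lists were of different relative length: 35437 peaks against 32176 and 37367 for FOXA1, 9029 against 16539 for HNF4A, and 22604 against 33528 and 29543 for AP2A. With lists of equal length the gains were 9.45 and 13.6 percentage points for FOXA1, 8.88 for HNF4A and 9.69 and 9.83 for AP2A, so kidney no longer had the largest gain in points; the ratios were not computed at equal length.

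Fewer factor peaks at AR sites in castrated animals were then weighed per tissue. A shorter castrated list was argued against as the whole cause: where the androgen-exposed list was longer, equal lengths left 13.6 points for FOXA1 replicate 2, 8.88 for HNF4A and at least 9.69 for AP2A, though HNF4A came down from 23.1 and AP2A replicate 1 from 15.4. The castrated FOXA1 list was longer than that of replicate 1, so length could not lower that comparison. A weaker castrated ChIP everywhere was argued against as the whole cause for AP2A. Within 5 score strata, AP2A peaks at AR sites were found in the castrated list less often than those elsewhere (highest odds ratio over replicates 0.36). The same held without the strata (0.791 and 0.741). For FOXA1 and HNF4A the highest odds ratios within the strata were 0.508 and 0.512. Without the strata the odds ratios were 1.13 and 0.915 for FOXA1 replicates 1 and 2, and 1.52 for HNF4A. Of peaks at AR sites, 66.8% of FOXA1 replicate 1 and 50.6% of HNF4A were in the castrated list, against 64.0% and 40.2% elsewhere. The scores came from the state that defined the AR sites, for AP2A as well, so the values within the strata cannot decide alone. For FOXA1 and HNF4A the test could therefore not decide. For AP2A the argument rests on the odds ratios without the strata. What stays open, untested, is hormone state itself, differences between the lone castrated list and the rest, and features that AR and factor lists of the same state share.

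The share of castrated AR peaks on AR sites differed by -47.6 percentage points between prostate and epididymis, and by -43.4 points between kidney and epididymis (95% interval -45.1 to -41.7). No explanation of the castrated kidney peaks was decided. The 6.63% of them on kidney AR sites is the pattern itself and tests nothing further. They met epididymal AP2A peaks, of another tissue and antibody, 19.0 percentage points more often than kidney AR sites (25.7% against 6.63%), or 17.9-fold against 8.19-fold above shifted positions, which allow for list length. They also met kidney AP2A (27.1%), prostate AR replicate 2 (21.9%) and prostate FOXA1 replicate 1 peaks (21.1%), but epididymal AR replicate 1 peaks at only 7.90%. No peak of the castrated kidney list had an FDR of 1% or less. The epididymal AP2A list was picked after its overlap was seen, so regions that come down with unrelated antibodies, AR binding at other places in castrated kidney and hormone regime all stay open.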

How the results depend on the processing

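The factor replicate lists alone, either factor replicate (outside the comparison of own and other factors), replicate 2 coordinates and the stricter tissue-only class were chosen after the data were seen. The comparisons of own and other factors (84 values), of castrated and androgen-exposed factor lists (60) and of AR enrichment (60) kept their direction and stayed past the threshold under every alternative run for them, while their sizes moved. Part of the 84 values could hardly come out otherwise. At an FDR of 1% or less, every other-factor list except kidney AP2A held 5 peaks or fewer. At a score of 100 or more the prostate HNF4A list held 0. Summits at most 200 bp apart and 100 bp each side of the summit are the same rule for matching. No paired analysis was possible because every comparison is between peak lists, with no model over samples that has a place for the shared replicate numbers. Gene lists and motifs, with their alternatives, were not run, since no mm9 annotation or sequence was used here; what counts as an AR site does not enter the enrichment test; and an FDR of 1% left no castrated kidney AR peaks. Total reads are not known, so what depth limits was not compared between lists.

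AR sites fell to 7644, 8293 and 14233 in prostate, kidney and epididymis at a score of 100 or more, and to 5307 in prostate at an FDR of 1% or less. Shared sites fell to 1148, 1128 and 1126 at that score, to 1161, 1151 and 1150 at that FDR, and to 910, 1021 and 1046 with 50% reciprocal overlap. By construction, the score and FDR rules leave fewer peaks to match, and the reciprocal rule admits fewer matches.

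The FOXA1 difference between prostate-only and shared sites turned to -3.53 points with 50% reciprocal overlap, -14.7 with the union of the AR replicates, and -18.9 to -7.65 with 1 replicate list alone. It rose to 16.0 points at an FDR of 1% or less, 12.2 at a score of 100 or more and 11.3 with equal lengths. The union brings in peaks found in 1 AR list only. The median score at prostate-only sites was 66.2 in replicate 1 alone, matched peaks included, and 110 with both replicates. Within 5 score strata the odds ratio was 1.74 in replicate 1 alone and 0.57 in replicate 2 alone, against 0.645 and 0.261 without strata. Score thus accounted for part of the reversal in replicate 2 but not for all of it. With 1 FOXA1 replicate list alone the difference was 5.50 to 6.83 points. The HNF4A difference was 1.17 points with the union. Apart from the score strata, the cause of these changes was not tested.

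For overlap over chance, draws from the union of all peaks gave 0.105 for HNF4A in prostate, 0.751 and 0.252 for FOXA1 in kidney and epididymis, and 0.0741 for HNF4A in epididymis. That union includes the tested factor list. FOXA1 in kidney was 7.58-fold at a score of 100 or more and HNF4A in prostate 2.21-fold with replicate 2 coordinates, neither past the threshold, and HNF4A in epididymis 0.569 and 0.594 by summits. Few sites lay behind these values. FOXA1 met 0.0121% of the kidney AR sites at that score, and HNF4A met 0.00897% of the epididymal sites by summits. Of the castrated prostate AR peaks, 0% lay on AR sites with 50% reciprocal overlap, the score, the FDR or equal lengths, where the score left 13 of them and the FDR left 1. The 2.44% was under chance with the union of AR replicates or of all peaks, as was the 6.63% of castrated kidney peaks with the union of all peaks.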

Other observations

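The cross-tissue lookups below were chosen after the data were seen. AP2A peaks of shorter lists were often found in the longer lists of other tissues. Of the 5653 prostate AP2A peaks, 74.7% were found in the epididymal replicate 1 list and 58.4% in kidney, and 51.9% of the kidney AP2A peaks were found in epididymis. Looked up in the same direction, from short to long lists, 7.19% of the kidney and 7.67% of the epididymal FOXA1 peaks were found in prostate replicate 1, and 2.32% of the prostate HNF4A peaks were found in kidney. From long to short lists, 12.8% of the epididymal AP2A peaks were found in prostate, 0.385% of the prostate FOXA1 peaks in kidney, 0.793% of them in epididymis and 0.163% of the kidney HNF4A peaks in prostate. The kidney FOXA1, epididymal FOXA1 and prostate HNF4A lists kept 5, 0 and 1 peaks at an FDR of 1% or less. The prostate AP2A list kept 3. Median lengths were 93, 91 and 92 bp in the former and 592 bp in prostate AP2A. The low shares of FOXA1 and HNF4A thus do not measure how far their binding is common to tissues. AP2A lay more often on shared than on tissue-only AR sites in the other tissues. The shares were 11.6% against 7.71% in prostate (Fisher's exact test, adjusted p = 4.7e-07) and 19.8% against 11.9% in kidney (exact test, adjusted p = 2.9e-17). FOXA1 did so as well outside prostate, on few sites. In kidney it lay on 22 shared and 47 tissue-only sites, 1.18% against 0.536% (exact test, adjusted p = 0.0054). In epididymis it lay on 19 and 45 sites, 1.02% against 0.301% (exact test, adjusted p = 8e-05). HNF4A outside kidney showed no such difference, with 0.0523% against 0.0516% in prostate and 0% against 0.0201% in epididymis. Shared sites had stronger AR peaks, and these contrasts were not repeated within score strata.

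Own-factor lists were also read at the tissue-only AR sites of the other tissues. Prostate FOXA1 peaks lay on 39.2% of prostate-only, 5.88% of kidney-only and 2.59% of epididymis-only AR sites. Kidney HNF4A peaks lay on 54.8% of kidney-only, 2.62% of prostate-only and 0.929% of epididymis-only sites. Epididymal AP2A peaks lay on 24.9% of epididymis-only, 9.4% of prostate-only and 7.26% of kidney-only sites. The smallest excess over shifted positions was 1.35-fold, for kidney HNF4A at epididymis-only sites (permutation by shifts, adjusted p = 0.002).

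Among the castrated lists, 30.8% of the epididymal AR peaks met epididymal replicate 1 AP2A peaks and 11.4% met prostate replicate 1 FOXA1 peaks. For the castrated kidney AR peaks, the share on the same AP2A list was close to this, at 31.4%, and that on the same FOXA1 list was higher, at 21.1%. Castrated kidney AR peaks were also longer (median 704 bp against 346 bp in epididymis), and longer peaks meet other lists more easily. These shares were not set against shifted positions.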
